A study of Mus musculus with 12 samples.

How the data were processed

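Total RNA was sequenced from the striatum of mice at 10.5 weeks of age, in 12 libraries. Per the labels, 2 genotypes on a B6CBA background, wild-type (WT) and R6/2, were crossed with 2 adeno-associated viruses, a control virus (C) and a virus carrying a short hairpin RNA against TRAX (T). The 4 groups are WT-C, WT-T, R6/2-C and R6/2-T, with 3 libraries each. Per the labels, virus was injected into both hemispheres at 5 weeks of age, 2 µl per spot at 2.5e9 vector genomes per µl. Per the labels' protocols, RNA was extracted with TRIzol or a miRNeasy kit, and which sample had which is not given in the sources used here. The library kit, TruSeq Stranded Total RNA Gold, marks the strand, but whether the counting used it is not given in the sources used here. The labels do not say that each library comes from a separate animal, so p-values measure the spread between libraries.

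Per the submitters' processing notes, bcl2fastq 2.20, HISAT2 and the genome build GRCm38 were used, with no version given for HISAT2. The deposited values of the main analysis are estimated counts per gene from StringTie, per the file headers, for 51912 genes. They are whole numbers, so that rounding changed nothing. The test design had assumed plain read counts, and the estimated counts were tested with the same method. StringTie counts summed to between 131783370 and 229332386 per library, with a median of 4.07 counts for each fragment, so these counts are not numbers of independent reads. A further 12 columns, headed Cuffdiff per the file headers, hold a deposited signal, which is fragment counts scaled to a common size. Dividing each column by the value of 1 fragment gave whole fragments within 0.05 for 95.1% to 97.1% of the values above 0. The recovered fragments, 32206237 to 57308868 per library, were used in an alternative analysis. A deposited table gives FPKM, fragments scaled for gene length and library depth, without naming the tool. Genes not detected are listed there at 1e-04 or lower, down to 1e-06. The authors also deposited a comparison of R6/2-T with R6/2-C for 626 genes described as neuron-enriched, with FPKM per library. Per the file headers that table gives the ratio of the mean FPKM, the log2 ratio, and a p-value and q-value. The authors' test and how neuron enrichment was defined are not given in the sources used here. Its FPKM equalled the FPKM table within 0.0001 for 625 genes and differed for 1, Snhg14, by up to 5.3. The 12 columns headed Pearson in the count table were not used.

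Genes were tested with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood F test with robust estimation and TMM scaling. The default expression filter by group left 23453 genes. All 12 libraries entered a single model of 4 group means. The contrasts were R6/2-C against WT-C, R6/2-T against R6/2-C, WT-T against WT-C, R6/2-T against WT-T, and the interaction, which is the shRNA change in R6/2 minus that in WT. Tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Levels are given as CPM, counts scaled to a common library size with the TMM factors. Gene symbols, identifiers and coordinates are those of the deposited tables, and GC content and transcript length come from the GENCODE annotation of GRCm38. These properties were found for 23354 genes and missing for 99.

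Before the data were examined, 30 gene lists were fixed. They cover striatal, cortical, glial, vascular, choroid plexus, blood and immune cell markers, immediate-early, signalling and postsynaptic genes, and genes of DNA repair, p53, small RNA, energy metabolism, ribosomes, cholesterol, stress, Hox and histones. Lists were tested with camera of limma 3.58.1, two-sided, at a preset correlation between genes of 0.01 and with Benjamini-Hochberg adjustment over the 30 lists. Camera with an estimated correlation and fry, a rotation test of whether a list moves on balance one way, were run beside it. Counts of called members are given over all genes tested and adjusted over the list alone. Some genes, such as Ano3, Homer1, Pde10a and Adora2a, belong to several lists.

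The rule for naming genes was also fixed before the data were examined. It takes Tsnax, Tsn, Disc1, Adora2a, Drd1, Drd2, Penk, Tac1, Ppp1r1b, Pde10a and Htt in every comparison. It adds the 10 called genes with the largest rise and the 10 with the largest fall among those with a mean log2 CPM of at least 1 whose libraries do not overlap between the groups. For the interaction, opposite signs or a 2-fold difference of the shRNA changes replaces the latter condition. Unnamed gene models are left out. The rule adds up to 4 called members of each list by smallest p and, where fewer than 5 genes are called, the 5 with the smallest p. For genes called in pairs of comparisons it takes the 5 of each kind with the smallest p. Some genes the rule takes are not reported here. Genes outside the rule are said to be chosen after their values were seen.

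The correlation of shRNA changes between genotypes was computed across all genes tested. For the genes called by genotype, the sign of the shRNA change in R6/2 was counted and set against 20 simulated data sets with no shRNA effect, because both contrasts share the R6/2-C libraries. Other splits of the libraries were refitted, 10 for each comparison of 3 with 3 libraries and 100 drawn from 200 for the interaction, of which 99 were counted.

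Alternatives chosen before the data were examined were the Wald test of DESeq2 1.42.0 with its size factors, RLE size factors, TMM scaling without mitochondrial, rRNA, snRNA and the 10 most abundant genes, no robust estimation, no expression filter, a filter of at least 1 CPM in 3 libraries, only the 2 groups compared, a replicate block, limma on log2 of FPKM plus 1 or plus 0.1 with and without a filter on low values, and leaving out each library in turn. Alternatives chosen after seeing the data were the recovered fragments, a correction for GC content and transcript length, 1 or 2 surrogate variables, counts divided by 4, the correlation over genes with a mean log2 CPM over 2, R6/2-C libraries divided between the genotype and the shRNA contrast, and the list tests and the overlap with the authors' table without each library in turn. The GC and length correction fitted a smooth surface per library with mgcv 1.9.3 on genes with a mean log2 CPM over 2. Surrogate variables came from sva 3.50.0.

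The test was run on simulated counts for 22907 genes with 200 genes changed between R6/2-T and R6/2-C. It recovered 25.4% of genes changed 1.5-fold, 67.2% of those changed 2-fold and 98.5% of those changed 4-fold, with 6 false calls. The simulation of WT-T against WT-C and of R6/2-C against WT-C, in which no gene was changed, gave 0 calls.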

Results

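The data are 12 libraries of total RNA from the mouse striatum, 3 in each of 4 groups. R6/2 mice carry the first exon of the human huntingtin gene with an expanded CAG repeat and model Huntington's disease. Each genotype received an adeno-associated virus (AAV), a viral vector that reaches neurons, with either a control or a short hairpin RNA (shRNA), which lowers the messenger RNA it matches. The shRNA was directed against TRAX, the translin-associated protein X encoded by Tsnax, which forms an RNA-cleaving complex with translin (Tsn). Libraries had 32206237 to 57308868 fragments and a mean r of 0.971 to 0.976 in log CPM within a group. R6/2-T pairs were closest (chi-square per degree of freedom 10.8 to 12.4, elsewhere 29.7 to 123), and tests pool the spread. Mitochondrial genes took 8.03% to 11.2% of the counts. The Y-linked gene Ddx3y had 50.7 to 97.0 CPM in every library and Xist had 0 to 82 counts, so that all libraries carried the male pattern.

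Tsnax (ENSMUSG00000056820, GRCm38 chromosome 8, 125012997 to 125034192, plus strand) was measured in every library to check the labels. It had 151, 152 and 167 CPM in WT-C, and 32.9, 27.6 and 33.6 CPM in WT-T. In R6/2 it had 197, 168 and 189 CPM with the control virus, and 44.7, 40 and 47 CPM with the shRNA. Each library thus lay on the side its label gives. Tsnax fell to 20% of its control level in WT (log2 −2.32, SE 0.11, edgeR adjusted p = 3.74e-06) and to 23.8% in R6/2 (log2 −2.07, SE 0.11, adjusted p = 1.18e-05). The shRNA changes of Tsnax did not differ by test between genotypes (interaction log2 0.25, SE 0.15, adjusted p = 0.52). Neither neighbour nor partner was called with the shRNA. Disc1, the next gene downstream on chromosome 8 (ENSMUSG00000043051, from 125054195 to 125261858), had a log2 change of −0.10 (SE 0.24) in WT and −0.28 (SE 0.24) in R6/2. Tsn (ENSMUSG00000026374, chromosome 1) had 0.02 (SE 0.09) and 0.14 (SE 0.09).

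**Figure D1:**
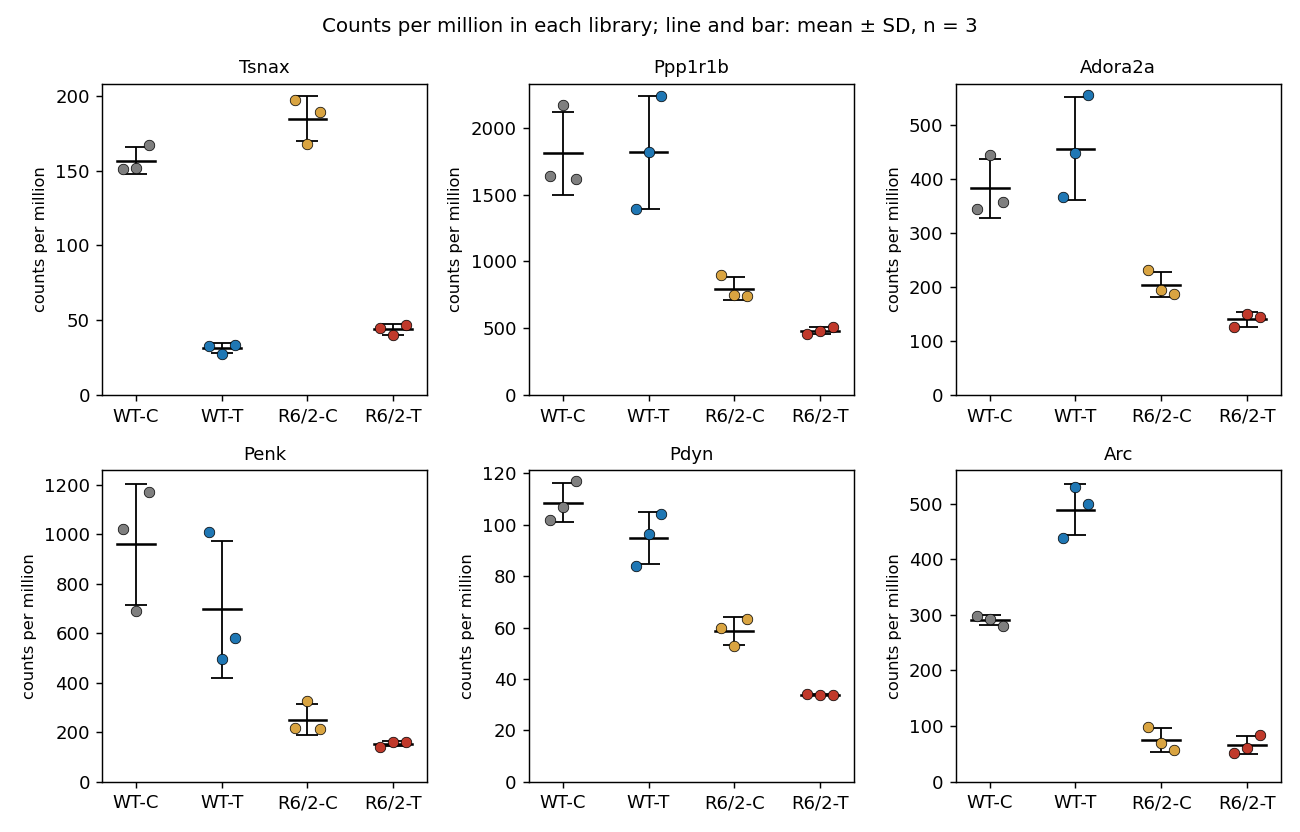
CPM of Tsnax, Ppp1r1b, Adora2a, Penk, Pdyn and Arc in each of the 12 libraries, by group, with the mean ± SD (n = 3) per group. Tsnax was between 27.6 and 47 CPM in every shRNA library and between 151 and 197 CPM in every control library.

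The comparison of R6/2-C with WT-C asked how the striatum of R6/2 mice differed from that of WT mice under the control virus. Genes that characterise medium spiny neurons, the projection neurons that make up most of the striatum, fell in R6/2-C. Scn4b, a sodium channel beta subunit, was 1380 ± 73.1 CPM in WT-C and 301 ± 18.6 in R6/2-C (SD, n = 3; log2 −2.20, SE 0.14, edgeR adjusted p = 3.84e-05). Penk, the precursor of the enkephalin peptides, fell from 962 ± 248 to 251 ± 63.8 CPM (log2 −1.94, SE 0.29, adjusted p = 0.00371). Arc, which neurons transcribe within minutes of synaptic activity, fell from 290 ± 9.36 to 74.8 ± 21 CPM (log2 −1.95, SE 0.21, adjusted p = 0.000889). In all, 2131 of 23453 genes were called, 1142 higher and 989 lower in R6/2-C. Their number was 454 when only these 2 groups were fitted, and 898, 921, 872, 876 and 803 without WT-C 1, WT-C 2, WT-C 3, R6/2-C 1 and R6/2-C 3. Most calls were lower, not higher, in 10 of 22 other fits, with 946 higher and 1007 lower by RLE size factors, 145 and 309 when only these 2 groups were fitted, 974 and 1269 with 1 surrogate variable and 345 and 527 without WT-C 3.

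Of 25 medium spiny neuron genes, 16 fell, 19 when adjusted over the list alone, and none rose. Their median log2 change was −0.95 (camera adjusted p = 2.52e-29, adjusted p = 0.064 with an estimated correlation). At the preset correlation, other splits of the 6 libraries, which keep part of the difference, called up to 21 lists. The p with an estimated correlation is given too, while fry called 9 lists, this and the immediate-early list at adjusted p = 0.00129. Ppp1r1b, a dopamine-regulated inhibitor of protein phosphatase, fell from 1810 ± 310 to 797 ± 88.2 CPM (log2 −1.18, SE 0.17). Rgs9, a regulator of G-protein signalling, had a log2 change of −1.20 (SE 0.10), Kcnip2, a potassium channel-interacting protein, −1.11 (SE 0.14), and Arpp21, a cAMP-regulated phosphoprotein, −0.96 (SE 0.10). Pde10a, the main striatal cyclic nucleotide phosphodiesterase, was not called by edgeR in StringTie counts (log2 −1.45, SE 0.52, adjusted p = 0.113), but was in recovered fragments (−1.49, adjusted p = 0.000594).

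Of the genes of indirect pathway neurons, 4 of 9 fell, 5 when adjusted over the list alone, with a median of −0.49 (camera adjusted p = 1.24e-05, adjusted p = 0.119 with an estimated correlation). They were Penk, the adenosine receptor Adora2a (log2 −0.90, SE 0.16, adjusted p = 0.00866), the dopamine receptor Drd2 (log2 −0.79, SE 0.15) and the orphan receptor Gpr6 (log2 −0.69, SE 0.17). Direct pathway genes went both ways, with 3 of 10 higher and 3 lower, or 4 and 4 when adjusted over the list alone, and a median of −0.04 (camera adjusted p = 0.313). The dopamine receptor Drd1 (log2 −0.74, SE 0.10), the muscarinic receptor Chrm4 (log2 −0.97, SE 0.21) and Pdyn, the precursor of the dynorphins (log2 −0.89, SE 0.10), fell, and the transcriptional coactivator Eya1 rose (log2 0.72, SE 0.16). Tac1, the substance P precursor, was not called (log2 0.36, SE 0.14, adjusted p = 0.129). Of 12 interneuron genes 4 fell, 7 when adjusted over the list alone, with a median of −0.50 (camera adjusted p = 0.00313, adjusted p = 0.281 with an estimated correlation). They were the acetylcholine genes Chat (log2 −0.62) and Slc18a3 (log2 −0.65), Kit (log2 −0.46) and the nitric oxide synthase Nos1 (log2 −1.29, but −0.64 with adjusted p = 0.0616 in recovered fragments). Of 10 cortical excitatory neuron genes edgeR called 0, over all genes or adjusted over the list alone, against 1 at an unadjusted p under 0.05 and 1 by DESeq2 (median 0.09, camera adjusted p = 0.734).

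Immediate-early genes, which neurons switch on with activity, fell in 12 of 18 cases, or 14 when adjusted over the list alone, with all 18 negative. Their median was −0.91 (camera adjusted p = 2.19e-17, adjusted p = 0.064 with an estimated correlation). Beside Arc, the transcription factor Npas4 (log2 −1.94, SE 0.34), the phosphatase gene Dusp1 (log2 −0.88, SE 0.13) and the postsynaptic scaffold gene Homer1 (log2 −0.90, SE 0.16) fell. Glutamate and postsynaptic genes fell in 4 of 24 cases, 9 when adjusted over the list alone, with a median of −0.34 (camera adjusted p = 5.1e-06, adjusted p = 0.572 with an estimated correlation). These 4 were Homer1, the scaffold genes Shank3 (log2 −1.22, SE 0.16) and Dlgap3 (log2 −0.81, SE 0.21), and the kainate receptor gene Grik2 (log2 −0.73, SE 0.09). In the cAMP list 5 of 24 fell and 2 rose, or 7 and 3 when adjusted over the list alone (median −0.15, camera adjusted p = 0.0873). Adcy5, the adenylyl cyclase of the striatum, fell from 1590 ± 143 to 667 ± 85.3 CPM, and Pde1b (log2 −0.71) and the adenosine receptor Adora1 (log2 −0.56) fell with it.

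Glial and vascular markers were lower as well. Of 15 astrocyte genes 8 fell, 12 when adjusted over the list alone, with a median of −0.57 (camera adjusted p = 1.61e-07). It was the only list called here by camera with an estimated correlation (adjusted p = 0.0275). The glutamate transporter gene Slc1a2 went from 2600 ± 626 to 1290 ± 327 CPM (log2 −1.01, SE 0.22), and the potassium channel gene Kcnj10 from 414 ± 24 to 251 ± 22.3 CPM (log2 −0.72, SE 0.11). Of 15 myelin genes 8 fell, 11 when adjusted over the list alone, with a median of −0.54 (camera adjusted p = 4.78e-10, adjusted p = 0.225 with an estimated correlation). Mal (log2 −0.95), Mobp (log2 −0.94) and Cldn11 (log2 −0.92), all components of myelin, and their regulator Myrf (log2 −0.55) were among them. Of 10 oligodendrocyte precursor genes 3 fell, 4 when adjusted over the list alone (median −0.28, camera adjusted p = 0.0183, adjusted p = 0.281 with an estimated correlation; median −0.20, camera adjusted p = 0.0929 after a correction for GC content and transcript length), namely Vcan (log2 −0.76), Cspg4 (log2 −0.61) and Gpr17 (log2 −0.51). Of 13 endothelial and mural genes 6 fell, 11 when adjusted over the list alone (median −0.58, camera adjusted p = 5.83e-07, adjusted p = 0.172 with an estimated correlation). They included Kcnj8 (log2 −0.83), the receptor genes Flt1 (log2 −0.76) and Kdr (log2 −0.72), and Pecam1 (log2 −0.58).

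Immune lists had negative medians with few called genes. Antigen presentation genes had a median of −0.86 (camera adjusted p = 0.0183, adjusted p = 0.69 with an estimated correlation), with 0 of 15 called by edgeR, 0 by DESeq2 and 0 at an unadjusted p under 0.05. Reactive glia and complement genes had −0.79 (camera adjusted p = 0.00112, adjusted p = 0.572 with an estimated correlation), with 1 of 17 called over all genes or the list alone, the small heat shock gene Hspb1 (log2 −0.98). Disease-associated microglia genes had −0.49 (camera adjusted p = 0.0162) and microglia markers −0.49 (camera adjusted p = 0.0449), each with adjusted p = 0.681 with an estimated correlation. Of their 18 and 16 members edgeR called 0, over all genes or the list alone, DESeq2 0 and 1, and 1 each had an unadjusted p under 0.05. Lymphocyte and granulocyte markers had −0.94 (camera adjusted p = 0.0175, adjusted p = 0.681 with an estimated correlation), with 1 called, 2 when adjusted over the list alone. That gene, the co-receptor gene Cd4, had 104 ± 2.9 CPM in WT-C against 3.37 ± 2.18 for Cd3e, and fell to 35 ± 6.47. Erythroid genes had −0.58 (camera adjusted p = 0.0342, adjusted p = 0.572 with an estimated correlation), with 0 of 6 called by edgeR, 1 by DESeq2 and 2 at an unadjusted p under 0.05. Interferon-stimulated genes had −0.36 (camera adjusted p = 0.109) and choroid plexus genes 1.11 (camera adjusted p = 0.55), with 0 called in either by edgeR or DESeq2, and 0 at an unadjusted p under 0.05. Without 1 library the interferon median went from −0.69 to 0.06 and the choroid plexus median from −0.66 to 1.49, so neither has a settled direction. The other medians went from −1.44 to −0.55 (antigen presentation), −1.09 to −0.42 (reactive glia), −0.90 to −0.15 (disease-associated microglia), −0.76 to −0.30 (microglia), −1.68 to −0.31 (lymphocyte) and −0.89 to −0.34 (erythroid).

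In nuclear oxidative phosphorylation genes 4 of 81 rose, but 0 when adjusted over the list alone, with a median of 0.16 (camera adjusted p = 0.00196, adjusted p = 0.69 with an estimated correlation). They were Atp5g1 (log2 0.45), Ndufv2 (log2 0.36), Atp5f1 (log2 0.32) and Uqcrc2 (log2 0.30). In the protein folding list 1 rose and 4 fell, or 5 and 8 when adjusted over the list alone (median −0.03, camera adjusted p = 0.272). The chaperone Hsp90aa1 went from 626 ± 21.5 to 912 ± 73.9 CPM, while Hspa1b (log2 −1.10), Dnajb5 (log2 −0.65) and the stress kinase-like gene Trib3 (log2 −1.28) fell. Cholesterol synthesis genes fell in 3 of 22 cases, over all genes or the list alone (median −0.15, camera adjusted p = 0.0508), among them Insig1 (log2 −0.64) and Fdft1 (log2 −0.28). Of 20 double-strand break repair genes 2 rose, over all genes or the list alone, Xrcc5 (log2 0.53) and Lig4 (log2 0.39), with a median of 0.05 (camera adjusted p = 0.314). Of 19 p53 targets 2 fell, 3 when adjusted over the list alone (median −0.21, camera adjusted p = 0.109). They were Ano3 (log2 −1.02), also on the medium spiny neuron list, and the cell cycle inhibitor Cdkn1a (log2 −0.97). In the small RNA list Ago4 fell (log2 −0.91, SE 0.12), the only 1 of 15 called, or 1 higher and 2 lower when adjusted over the list alone (median −0.11, or 0.09 after a correction for GC content and transcript length, camera adjusted p = 0.397). Mitochondrially encoded genes (median 0.05, or −0.08 after it, camera adjusted p = 0.761), ribosomal protein genes (median 0.04, or −0.01 after it, camera adjusted p = 0.397), the 8 Hox genes tested (median 1.11 but −0.41 in recovered fragments, camera adjusted p = 0.182) and replication-dependent histones (median −0.16, camera adjusted p = 0.872) had 0 genes called by edgeR. DESeq2 called 0, 1, 1 and 2 of them, and 0, 3, 1 and 3 had an unadjusted p under 0.05. Of the 16 lists called at the preset correlation, 9 were called without any 1 library. The microglia, oligodendrocyte precursor, lymphocyte, erythroid, antigen presentation, disease-associated microglia and nuclear oxidative phosphorylation lists were not, with a camera adjusted p of up to 0.242, for microglia markers without R6/2-C 1, and an oxidative phosphorylation median of 0.03 to 0.24. The medians of the direct pathway, cortical, repair, mitochondrially encoded, ribosomal, protein folding and histone lists changed sign without 1 library.

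Among the largest changes, Ryr1, the skeletal muscle calcium release channel, fell from 97.7 ± 3.67 to 7.88 ± 1.31 CPM (log2 −3.63, SE 0.20, adjusted p = 2.36e-05). The transcription factor Mafa (log2 −3.18), the growth factor Fgf3 (log2 −2.85), Slc4a11 (log2 −2.72), Egr2 (log2 −2.72) and Sec14l3 (log2 −2.36) fell too. Abhd11os had a log2 change of −3.62, but it is an opposite-strand gene whose reads cannot be told from those of its partner without knowing the strand setting, as is Mccc1os (log2 1.81). The immunoglobulin genes Igkv6-23 (log2 −5.88) and Iglv3 (log2 −8.30) belong to a family of near copies and varied within WT-C, with 9.9 ± 16.5 CPM of Iglv3. Wt1, a transcription factor of kidney and gonad development, rose from 0.569 ± 0.204 to 5.77 ± 1.13 CPM (log2 3.33, SE 0.42, adjusted p = 0.00172). Tmc3 (log2 2.34), AW495222 (log2 2.06), the protocadherin Pcdh20 (log2 1.72), Lrrtm4 (log2 1.52), Fibin (log2 1.41) and Zmat1 (log2 1.36) rose. Btbd6 (log2 2.11) and Fiz1 (log2 1.36) were called in StringTie counts but not in recovered fragments (0.24 and 0.18), and in those Mccc1os, Lrrtm4 and Zmat1 moved by 0.90, 0.63 and 0.39. Htt itself was not called (log2 −0.16, SE 0.15, adjusted p = 0.559). Among the named genes of this comparison, calls ended by leaving out 1 library included those of Agt, Ano3, Atp5f1, Atp5g1, Btbd6, Cdkn1a, Chat, Chrm4, Cspg4, Dlgap3, Egr2, Eya1, Fdft1, Fibin, Fiz1, Flt1, Gpr17, Gpr6, Igkv6-23, Iglv3, Insig1, Kit, Lig4, Mccc1os, Ndufv2, Nos1, Pecam1, Slc18a3, Slc1a2, Trib3, Uqcrc2, Vcan, Xrcc5 and Zmat1. Their adjusted p in those fits lay between 0.0508 (Gpr17 without R6/2-C 2) and 0.165 (Fdft1 without WT-C 1), and all kept their direction. The GC and length correction ended the calls of Uqcrc2 (0.19), Atp5f1 (0.17), Ndufv2 (0.23), Cspg4 (−0.24), Wnk1 (−0.35), Gpr17 (−0.36), Nos1 (−0.95), Lig4 (0.31), Chat (−0.57), Agt (−0.71), Fdft1 (−0.23) and Cdkn1a (−0.94).

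The comparison of R6/2-T with R6/2-C asked what lowering TRAX changed in the R6/2 striatum. Beside Tsnax, few genes passed the test. Pdyn fell from 58.7 ± 5.43 to 33.8 ± 0.23 CPM (SD, n = 3; log2 −0.80, SE 0.10, edgeR adjusted p = 0.0292). Nptx2, a neuronal pentraxin that gathers glutamate receptors at synapses, fell from 13.6 ± 3.09 to 5.61 ± 0.704 CPM (log2 −1.28, SE 0.18, adjusted p = 0.0401). Slc5a3, a sodium-coupled inositol transporter, rose from 33 ± 4.36 to 59.2 ± 2.08 CPM (log2 0.84, SE 0.12, adjusted p = 0.0401). Phf3, a PHD finger protein, rose from 46.8 ± 7.7 to 155 ± 8.59 CPM in StringTie counts (log2 1.72, SE 0.14, adjusted p = 0.00073), but its change was 0.42 in recovered fragments (adjusted p = 0.0561).

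In all 16 genes were called by edgeR on StringTie counts, 12 higher and 4 lower, against 4513 at an unadjusted p under 0.05. Most calls were lower in 7 of 22 other fits, with 6 higher and 12 lower with 1 surrogate variable. Other tools called more: 1664 genes by DESeq2 (996 higher), 507 in recovered fragments, 52 by limma on log2 FPKM plus 1 (23 higher) and 185 with a filter on FPKM (101 higher). The RNA-binding protein gene Cpeb4 (log2 0.77), the deubiquitinase gene Otud4 (log2 0.65), Zfp955b (log2 0.94), Dnajc27 (log2 0.76), Fam199x (log2 0.66), the chromatin remodelling gene Ino80d (log2 0.65) and the kinase gene Wnk1 (log2 0.71) rose. Fkbp1a, which binds calcium release channels, fell (log2 −1.20, SE 0.18), with −0.30 in recovered fragments (adjusted p = 0.131). The called genes outside the naming rule were Gm16638 (log2 0.87), Gm16485 (log2 1.21) and 2610203C20Rik (log2 0.75), named after their values were seen. After correction for GC content and transcript length 6 of the 16 were still called. The changes of the others were 0.07 for Ino80d, 0.25 for Wnk1, 0.30 for Fam199x, 0.34 for Otud4, 0.38 for Slc5a3, 0.50 for Gm16638, 0.51 for Cpeb4, 0.66 for 2610203C20Rik, 0.72 for Zfp955b and −0.99 for Fkbp1a. The count was 4, 2, 4, 2 and 2 without R6/2-C 1, R6/2-C 3, R6/2-T 1, R6/2-T 2 and R6/2-T 3, and 1197 without R6/2-C 2. Tsnax was called in every one of these fits, and Phf3 in every one but that on recovered fragments. The other 11 genes of the naming rule lost the call without R6/2-C 1, without R6/2-C 3 or without any R6/2-T library.

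The fixed striatal genes had mostly negative changes, none called by edgeR in StringTie counts. Ppp1r1b had a log2 change of −0.73 (SE 0.17, adjusted p = 0.0839), Adora2a −0.55 (SE 0.16, adjusted p = 0.114), Drd2 −0.50 (SE 0.15, adjusted p = 0.129), Penk −0.71 (SE 0.28, adjusted p = 0.2), Tac1 −0.41 (SE 0.14, adjusted p = 0.156) and Drd1 −0.22 (SE 0.10, adjusted p = 0.267). Ppp1r1b and Adora2a were called in recovered fragments (adjusted p = 0.0431 and 0.0485). Htt had 0.47 (SE 0.15, adjusted p = 0.148) and Pde10a 0.04 (SE 0.51, adjusted p = 0.977). With the preset correlation 18 of 30 lists were called, 4 higher and 14 lower, and none with an estimated one (lowest adjusted p = 0.47). The medium spiny neuron list had a median of −0.25 (camera adjusted p = 8.22e-05, adjusted p = 0.475 with an estimated correlation), with 0 of 25 called, 8 lower when adjusted over the list alone, 12 at an unadjusted p under 0.05 and 5 by DESeq2. Indirect pathway genes had −0.36 (camera adjusted p = 0.0307, adjusted p = 0.47 with an estimated correlation), with 0 of 9 called, 2 lower when adjusted over the list alone, 4 at an unadjusted p under 0.05 and 1 by DESeq2. Direct pathway genes had −0.14 (camera adjusted p = 0.0824), with Pdyn called over all genes and the list alone. Immediate-early genes had −0.56 (camera adjusted p = 6.41e-06, adjusted p = 0.47 with an estimated correlation), with 0 of 18 called, 7 lower when adjusted over the list alone, 8 at an unadjusted p under 0.05 and 6 by DESeq2.

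Interferon-stimulated genes, induced by antiviral signalling, were lower in all 25 cases in R6/2-T, with a median of −1.71 (camera adjusted p = 4.88e-16, adjusted p = 0.47 with an estimated correlation). edgeR called 0 of them over all genes and 24 when adjusted over the list alone, DESeq2 called 16, and 24 had an unadjusted p under 0.05. Cxcl10, a T cell attractant, had 29.5 ± 17.2 and 3.57 ± 2.13 CPM (log2 −3.05, SE 0.64, adjusted p = 0.0726). The other immune lists moved the same way. Lymphocyte and granulocyte markers had a median of −2.30 (camera adjusted p = 6.41e-06, 2 lower adjusted over the list alone), antigen presentation genes −1.73 (camera adjusted p = 1.11e-06, 0 adjusted over the list alone) and reactive glia genes −1.10 (camera adjusted p = 1.13e-07, 8 lower adjusted over the list alone). Each had adjusted p = 0.47 with an estimated correlation and 0 called over all genes, against 4, 2 and 8 by DESeq2 and 7, 9 and 9 at an unadjusted p under 0.05. Disease-associated microglia genes had −0.72 (camera adjusted p = 7.53e-05) and microglia markers −0.63 (camera adjusted p = 0.00172), both with adjusted p = 0.475 with an estimated correlation. edgeR called 0 in either, over all genes or the list alone, DESeq2 3 and 4, and 8 lower genes in each had an unadjusted p under 0.05. The mean interferon level of the R6/2-T libraries, centred over all libraries on the log2 scale, was −2.12, −1.3 and −0.78, and that of R6/2-C −0.82, 0.53 and 0.9, so that the groups overlapped.

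**Figure D2:**
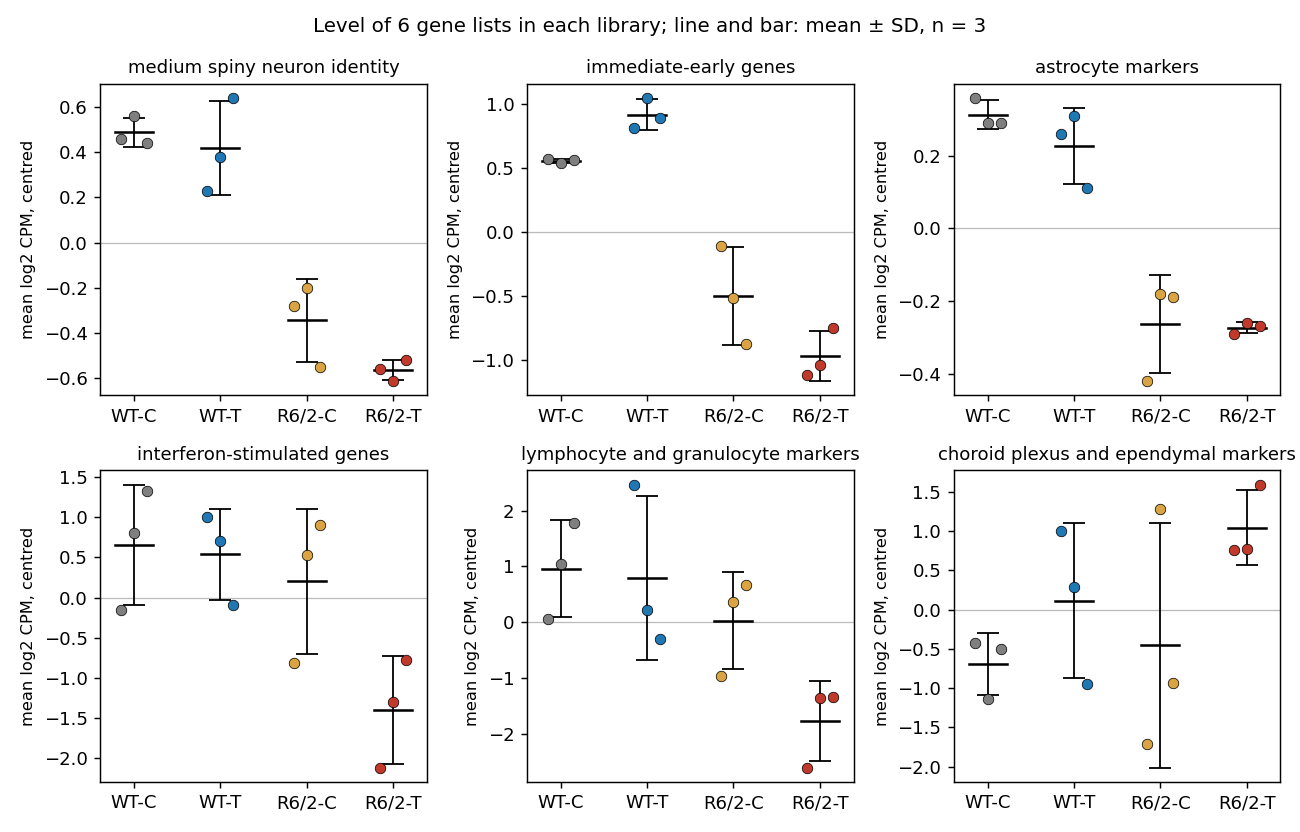
Level of 6 gene lists in each of the 12 libraries, as the mean log2 CPM of the members centred over all libraries, with the mean ± SD (n = 3) per group. Interferon and lymphocyte levels were lowest in R6/2-T and spread widely within every group, from −0.15 to 1.33 for interferon in WT-C.

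Genes of the small RNA machinery were higher in 14 of 15 cases with a median of 0.36 (camera adjusted p = 2.8e-07), 0 called over all genes, 9 when adjusted over the list alone, 6 by DESeq2 and 10 at an unadjusted p under 0.05. After the GC and length correction that median was 0.06 (camera adjusted p = 0.0965). Double-strand break repair genes had a median of 0.21 (camera adjusted p = 0.00188), 0 called over all genes, 6 higher when adjusted over the list alone, 5 by DESeq2 and 8 at an unadjusted p under 0.05, and a median of 0.07 after that correction (camera adjusted p = 0.419). Glutamate and postsynaptic genes had 0.17 (camera adjusted p = 0.00173), 0 called over all genes, 2 higher when adjusted over the list alone and by DESeq2 and 4 at an unadjusted p under 0.05, and 0.03 after it (camera adjusted p = 0.646). Ribosomal protein genes, which have near-identical pseudogene copies, were lower in 78 of 81 cases with a median of −0.36 (camera adjusted p = 3.06e-13), 0 called over all genes, 8 lower when adjusted over the list alone, 9 by DESeq2 and 25 at an unadjusted p under 0.05, and −0.16 after it. Nuclear oxidative phosphorylation genes had −0.16 (camera adjusted p = 0.00159), 0 called over all genes or the list alone, 2 by DESeq2 and 13 at an unadjusted p under 0.05, and 0.07 after it (camera adjusted p = 0.128). With an estimated correlation the adjusted p was 0.61 for the glutamate, 0.687 for the oxidative phosphorylation and 0.47 for the other 3 lists. Across 13210 genes the shRNA change in R6/2 correlated with transcript length at a Spearman rho of 0.555 and with GC content at −0.345, genes not being independent replicates.

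Myelin genes had a median of −0.18 (camera adjusted p = 0.0489), p53 targets −0.26 (camera adjusted p = 0.00521) and protein folding genes −0.15 (camera adjusted p = 0.025), or 0.03 after the correction (camera adjusted p = 0.342), with adjusted p = 0.677, 0.47 and 0.47 with an estimated correlation. Over all genes edgeR called 0 of each, against 0, 2 and 3 by DESeq2 and 3, 4 and 4 at an unadjusted p under 0.05. Adjusted over the list alone 0, 0 and 3 were called. Choroid plexus genes had 0.92 (camera adjusted p = 0.0109, adjusted p = 0.539 with an estimated correlation), with 0 called by edgeR or DESeq2 and 0 at an unadjusted p under 0.05. The 12 lists not called had camera adjusted p from 0.0824 to 0.832. Of the 18 lists called, 11 were called without any 1 library. The indirect pathway, microglia, myelin, choroid plexus, p53, oxidative phosphorylation and protein folding lists were not, with a camera adjusted p of up to 0.541, for oxidative phosphorylation genes without R6/2-C 1. Medians without 1 library went from −0.65 to −0.24 for immediate-early, −2.68 to −1.44 for lymphocyte, −2.09 to −0.95 for antigen presentation, −0.93 to −0.37 for disease-associated microglia, −0.81 to −0.32 for microglia, 0.43 to 2.65 for choroid plexus, −0.46 to −0.23 for indirect pathway, −0.25 to −0.09 for myelin, −0.23 to −0.06 for oxidative phosphorylation and −0.22 to −0.07 for protein folding genes.

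The authors' own table of R6/2-T against R6/2-C lists 626 genes, 379 higher and 247 lower, with p up to 0.0496 and q under 0.05 for 291. Of these 626, 68 are marked significant (23 higher, 45 lower), the ones with an absolute log2 ratio of at least 1. All 622 genes that were tested here had the same sign, and 4 were called here, Tsnax, Dnajc27, Otud4 and Slc5a3, against 101 in recovered fragments. Without R6/2-C 2 the overlap was 180, without R6/2-C 1 it was 2, and without any other of the 6 libraries it was 1. The table rests on the same libraries and is not independent evidence.

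The comparison of WT-T with WT-C asked what lowering TRAX changed without the disease gene. Tsnax was the only gene called by edgeR, against 1512 genes at an unadjusted p under 0.05, 101 called by DESeq2 (37 higher) and 4 in recovered fragments. Next by p came Pcdh20, a cell adhesion gene, with 8.71 ± 0.498 CPM in WT-C and 3.28 ± 0.807 in WT-T (SD, n = 3; log2 −1.41, SE 0.17, adjusted p = 0.0555), but 0.44 in recovered fragments. Tm9sf4, a membrane protein gene, had a log2 change of −0.57 (SE 0.07, adjusted p = 0.0558) and was called in recovered fragments (−0.58, adjusted p = 0.0132). Tusc3, an oligosaccharyltransferase subunit gene, had −0.69 (SE 0.10, adjusted p = 0.107), and Mocs1, of molybdenum cofactor synthesis, −1.11 (SE 0.16, adjusted p = 0.107), with −0.03 in recovered fragments. The count was 11 without WT-T 1, and 2 without each of WT-C 1, WT-T 2 and WT-T 3.

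None of the striatal genes of the naming rule was called in WT-T, with log2 changes of 0.01 (SE 0.17) for Ppp1r1b, 0.06 (SE 0.15) for Drd2, 0.02 (SE 0.10) for Drd1, 0.25 (SE 0.16) for Adora2a, −0.01 (SE 0.14) for Tac1, −0.24 (SE 0.51) for Pde10a, −0.46 (SE 0.28) for Penk and 0.00 (SE 0.15) for Htt. Their adjusted p lay between 0.873 and 1. With the preset correlation 7 of 30 lists were called, each with adjusted p = 0.997 with an estimated correlation. Immediate-early genes had a median of 0.36 (camera adjusted p = 4.7e-06), 2 higher when adjusted over the list alone and 6 at an unadjusted p under 0.05. Choroid plexus genes had 0.95 (camera adjusted p = 0.00467). Histone genes, which include near-identical copies, had 0.22 (camera adjusted p = 0.00272), but 0.09 in recovered fragments (camera adjusted p = 0.424), and nuclear oxidative phosphorylation genes 0.08 (camera adjusted p = 0.0368). Myelin genes had −0.21 (camera adjusted p = 0.00235), reactive glia genes −0.29 (camera adjusted p = 0.00467) and antigen presentation genes −0.35 (camera adjusted p = 0.0368, or 0.0635 in recovered fragments). Of all 7 lists, edgeR over all genes and DESeq2 called 0 members, and in the 6 lists beside the immediate-early only 7 histone genes had an unadjusted p under 0.05. Adjusted over the list alone 0 were called in those 6. Only the immediate-early list of these 7 was called without any 1 library, with a camera adjusted p of up to 0.000238. Antigen presentation genes had medians of 0.04 without WT-C 3 and 0.02 without WT-T 3 (camera adjusted p = 0.524 and 0.888), and oxidative phosphorylation genes −0.02 without WT-T 1 (camera adjusted p = 0.677). Without 1 library the reactive glia median went from −0.68 to −0.12, the histone from 0.06 to 0.55, the choroid plexus from 0.50 to 1.37 and the myelin from −0.31 to −0.11. Interferon-stimulated genes had a median of −0.18 (camera adjusted p = 0.465), from −0.50 to 0.14 in these fits.

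The comparison of R6/2-T with WT-T asked how the genotypes differed with TRAX lowered in both. Medium spiny neuron genes fell again. Scn4b was 1460 ± 250 CPM in WT-T and 206 ± 28.4 in R6/2-T (SD, n = 3; log2 −2.82, SE 0.15, edgeR adjusted p = 5.85e-06), and Ppp1r1b fell from 1820 ± 421 to 482 ± 28.7 CPM (log2 −1.92, SE 0.18, adjusted p = 0.000138). Arc fell from 489 ± 46.2 to 65.7 ± 16.8 CPM (log2 −2.90, SE 0.22, adjusted p = 4.14e-05). Immune transcripts were lower as well, with Cxcl10 falling from 50.3 ± 14.3 to 3.57 ± 2.13 CPM (log2 −3.82, SE 0.66, adjusted p = 0.00346). In all 5304 genes were called, 2705 higher and 2599 lower. The count was 2760, 3149 and 3399 without R6/2-T 1, R6/2-T 3 and WT-T 2, and most calls were lower in 4 of 22 other fits.

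Of 25 medium spiny neuron genes 16 fell and 1 rose, or 18 and 1 when adjusted over the list alone, with a median of −1.05 (camera adjusted p = 8.91e-27, adjusted p = 0.106 with an estimated correlation). Syndig1l (log2 −1.63, SE 0.14), the GTPase gene Rasd2 (log2 −1.62, SE 0.15) and Rgs9 (log2 −1.48, SE 0.10) were among them. Indirect pathway genes fell in 5 of 9 cases, 6 when adjusted over the list alone (median −0.82, camera adjusted p = 1.14e-06, adjusted p = 0.106 with an estimated correlation), with Penk (log2 −2.18), Adora2a (log2 −1.71), Drd2 (log2 −1.35) and Gpr6 (log2 −1.27). Of 10 direct pathway genes 5 fell and 2 rose, or 5 and 4 when adjusted over the list alone (median −0.17, camera adjusted p = 0.0547): Pdyn (log2 −1.49), Chrm4 (log2 −1.51) and Drd1 (log2 −0.98) fell and Ebf1 rose (log2 0.79). Interneuron genes fell in 5 of 12 cases, 7 when adjusted over the list alone (median −0.67, camera adjusted p = 0.00256, adjusted p = 0.329 with an estimated correlation), with Slc18a3 (adjusted p = 0.00233), Npy (log2 −0.76), Chat (log2 −0.70) and Kit (log2 −0.40). All 18 immediate-early genes fell, over all genes and the list alone, with a median of −1.84 (camera adjusted p = 5.93e-32). This list alone was called with an estimated correlation (adjusted p = 0.0273), against 19 lists by fry. It includes Junb (log2 −2.59), Dusp1 (log2 −1.46) and Ier5 (log2 −1.27). In the cAMP list 5 fell and 3 rose, 7 and 5 when adjusted over the list alone (median −0.06, camera adjusted p = 0.109). Glutamate genes fell in 4 cases and rose in 2, or 6 and 2 when adjusted over the list alone (median −0.18, camera adjusted p = 0.132).

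Of 25 interferon-stimulated genes 16 fell, 22 when adjusted over the list alone, with a median of −1.74 (camera adjusted p = 1.96e-09). Mx1 went from 21.4 ± 10.5 to 1.37 ± 0.712 CPM (log2 −3.96, SE 0.74), and Zbp1 (log2 −3.33) and Bst2 (log2 −2.23) fell. Antigen presentation genes fell in 8 of 15 cases, 12 when adjusted over the list alone (median −2.22, camera adjusted p = 0.000106), with Cd74 (log2 −3.58), Nlrc5 (log2 −2.22), Tapbp (log2 −1.41) and H2-T23 (log2 −2.53), which has near copies. Lymphocyte markers fell in 9 of 15 cases, 13 when adjusted over the list alone (median −3.26, camera adjusted p = 9.7e-06), with Cd8b1 (log2 −4.44), Gzmb (log2 −4.20) and Cd4 (log2 −2.55, SE 0.19). Reactive glia genes fell in 9 of 17 cases, 13 when adjusted over the list alone (median −1.27, camera adjusted p = 3.83e-06), with Ccl2 (log2 −4.11), Socs3 (log2 −2.62), Cebpd (log2 −2.44) and Hspb1 (log2 −0.97). Microglia markers fell in 9 of 16 cases, over all genes and the list alone (median −0.94, camera adjusted p = 0.000223), with C1qb (log2 −2.31), C1qc (log2 −2.26), Trem2 (log2 −1.55) and Tmem119 (log2 −1.25). Disease-associated microglia genes fell in 8 of 18 cases, 15 when adjusted over the list alone (median −1.47, camera adjusted p = 9.7e-06), with Ccl4 (log2 −3.19), Ch25h (log2 −1.96), Cd68 (log2 −1.50) and Axl (log2 −1.04). With an estimated correlation the adjusted p was 0.448 for antigen presentation, 0.329 for lymphocyte and reactive glia, and 0.364 for the other 3 lists. Levels varied within WT-T, where Cd74 had 658 ± 716 CPM.

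Astrocyte genes fell in 6 of 15 cases, 7 when adjusted over the list alone (median −0.40, camera adjusted p = 0.00162, adjusted p = 0.125 with an estimated correlation), with Agt (log2 −0.79), Aldh1l1 (log2 −0.52), Kcnj10 (log2 −0.49) and Slc1a3 (log2 −0.38). Myelin genes fell in 9 of 15, 10 when adjusted over the list alone (median −0.55, camera adjusted p = 3.84e-06, adjusted p = 0.329 with an estimated correlation), with Cldn11 (log2 −1.14), Mobp (log2 −0.85) and Myrf (log2 −0.47). Precursor genes fell in 3 of 10, 4 when adjusted over the list alone (median −0.22, camera adjusted p = 0.387). Endothelial and mural genes fell in 5 of 13, over all genes and the list alone (median −0.32, camera adjusted p = 0.0102, adjusted p = 0.364 with an estimated correlation), with Cldn5 (log2 −0.90), Kcnj8 (log2 −0.69), Pecam1 (log2 −0.53) and Slc2a1 (log2 −0.32). Erythroid genes fell in 4 of 6, over all genes and the list alone (median −1.23, camera adjusted p = 0.00162, adjusted p = 0.329 with an estimated correlation). These are the globin genes Hba-a1 (log2 −1.22), Hba-a2 (log2 −1.23), Hbb-bs (log2 −1.39) and Hbb-bt (log2 −1.42), near copies in pairs. In the choroid plexus list (median 1.12, camera adjusted p = 0.399) and the cortical list (median −0.50, camera adjusted p = 0.453) 1 gene each fell, namely Foxj1 (log2 −0.59, −0.11 after the GC and length correction) and Fezf2 (log2 −0.72, or −0.41), with 0 when adjusted over the list alone.

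Of 19 p53 targets 11 fell, over all genes and the list alone (median −0.49, camera adjusted p = 0.0017), with Cdkn1a (log2 −1.83), Bbc3 (log2 −1.36), Phlda3 (log2 −0.99) and Aen (log2 −0.33). Of 20 repair genes 6 rose, or 9 with 1 lower when adjusted over the list alone (median 0.34, camera adjusted p = 0.0017), with Prkdc (log2 0.75), Rif1 (log2 0.75), Xrcc5 (log2 0.56) and Lig4 (log2 0.55). Of 15 small RNA genes 5 rose and 1 fell, or 6 and 1 when adjusted over the list alone (median 0.20, camera adjusted p = 0.0216), with Ddx6 (log2 1.41), Dgcr8 (log2 0.51), Xpo5 (log2 0.41) and Ago4 (log2 −0.88). Tsn rose (log2 0.37, SE 0.09, adjusted p = 0.0135) and Tsnax was higher in R6/2-T (log2 0.49, SE 0.10, adjusted p = 0.00757, or 0.0504 without R6/2-T 3). Protein folding genes fell in 9 of 19 cases and rose in 4, or 10 and 4 when adjusted over the list alone (median −0.28, camera adjusted p = 0.0192), with Trib3 (log2 −1.87), Hspa1b (log2 −1.20), Dnajb5 (log2 −0.84) and Hsp90aa1 (log2 0.71). Cholesterol genes fell in 5 of 22 and rose in 1, over all genes and the list alone (median −0.21, camera adjusted p = 0.0547). Nuclear oxidative phosphorylation genes went both ways, 5 of 81 higher and 4 lower, or 5 and 3 when adjusted over the list alone (median −0.08, or 0.06 after the GC and length correction, camera adjusted p = 0.453). Ribosomal protein genes fell in 14 of 81 cases and rose in 1, over all genes and the list alone (median −0.40, camera adjusted p = 1.83e-05), with Rpl3l (log2 −3.01), Rpl37a (log2 −0.77) and Rps14 (log2 −0.57). Histone genes fell in 9 of 64, 8 when adjusted over the list alone (median −0.46, camera adjusted p = 0.0159), with Hist1h2bc (log2 −1.12), Hist1h1c (log2 −0.92), Hist1h2bg (log2 −0.90) and Hist1h2ad (log2 −1.53). Mitochondrially encoded genes (median 0.00, camera adjusted p = 0.625) and Hox genes (median 1.03 but −0.80 in recovered fragments, camera adjusted p = 0.57) had 0 called by edgeR, 0 and 2 by DESeq2, and 0 and 3 at an unadjusted p under 0.05. With an estimated correlation the adjusted p was 0.329 for the p53 and repair, 0.408 for the small RNA, 0.364 for the protein folding and 0.572 for the ribosomal and histone lists. Of the 20 lists called at the preset correlation, the small RNA, ribosomal and protein folding lists were not called without WT-T 1 (camera adjusted p = 0.099, 0.0595 and 0.0591). Medians without 1 library went from −3.83 to −1.92 for lymphocyte, −2.58 to −1.31 for antigen presentation, −1.77 to −0.91 for disease-associated microglia, −0.55 to −0.15 for ribosomal and −0.34 to −0.18 for protein folding genes. After the GC and length correction 4 were not called: the repair list (median 0.17, camera adjusted p = 0.0834), the small RNA list (median 0.09, camera adjusted p = 0.439), the protein folding list (median −0.22, camera adjusted p = 0.123) and the histone list (median −0.29, camera adjusted p = 0.0709). In recovered fragments the small RNA list (median 0.24, camera adjusted p = 0.0968) and the histone list (median −0.18, camera adjusted p = 0.384) were not called. Across 13210 genes the changes correlated with GC content at a Spearman rho of −0.514 and with transcript length at 0.272, genes not being independent replicates.

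Among the largest rises were Pcdh20 (log2 3.63, or 1.78 in recovered fragments), Wt1 (log2 3.59), Tmc3 (log2 2.56), Klhl14 (log2 2.01), Ttbk2 (log2 1.99, or 0.74), Phf3 (log2 1.90, or 0.54), Nek7 (log2 1.78, or 0.48), Sfmbt2 (log2 1.74) and Zfx (log2 1.63, or 0.66). Sec14l3 fell from 12.8 ± 5.8 to 0.683 ± 0.235 CPM (log2 −4.23, SE 0.36, adjusted p = 9.74e-05). The other large falls were in immune genes: Acod1 (log2 −4.53), H2-Ea-ps (log2 −4.71), Cd8a (log2 −4.11), Cd3g (log2 −4.21) and the immunoglobulin genes Igha (log2 −4.36), Ighg1 (log2 −7.01) and Ighv1-81 (log2 −6.40), the last from families of near copies. Disc1 fell (log2 −0.85, adjusted p = 0.0277), and Htt (log2 0.31, adjusted p = 0.176), Tac1 (log2 −0.04, adjusted p = 0.872) and Pde10a (log2 −1.16, adjusted p = 0.134, but −1.51 with adjusted p = 0.000169 in recovered fragments) were not called. Leaving out 1 library, R6/2-T 1 most often, ended the calls of 42 named genes. The highest adjusted p was 0.187 (Cd3g without WT-T 1), and Cd74 and Cd8a had 0.115 and 0.114 without WT-T 1. Calls ended by the GC and length correction included those of Tsn (0.09), Slc2a1 (−0.11), Myrf (−0.20), Rif1 (0.24), Lig4 (0.24), Disc1 (−0.45), Cldn5 (−0.47), Agt (−0.48), Aldh1l1 (−0.33), Phlda3 (−0.50), Bbc3 (−0.73), Tapbp (−1.08), Tmem119 (−0.85), Axl (−0.87), Zfx and Ttbk2 (1.16 or more), Rpl37a (−0.41), Rps14 (−0.27) and Chat (−0.47). The fit on recovered fragments ended those of Hba-a2 (adjusted p = 0.0706) and Hist1h2bg (−0.46).

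The genotype differences with and without the shRNA share no library and ran alike. Of all genes 805 were called higher in both, where independent lists of these sizes would share 132, and 639 lower in both, where they would share 110. The signs were opposite for 3 called genes, against 241 for independent lists. The log2 changes correlated across genes at r = 0.467 and rho = 0.548, genes not being independent replicates.

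**Figure D3:**
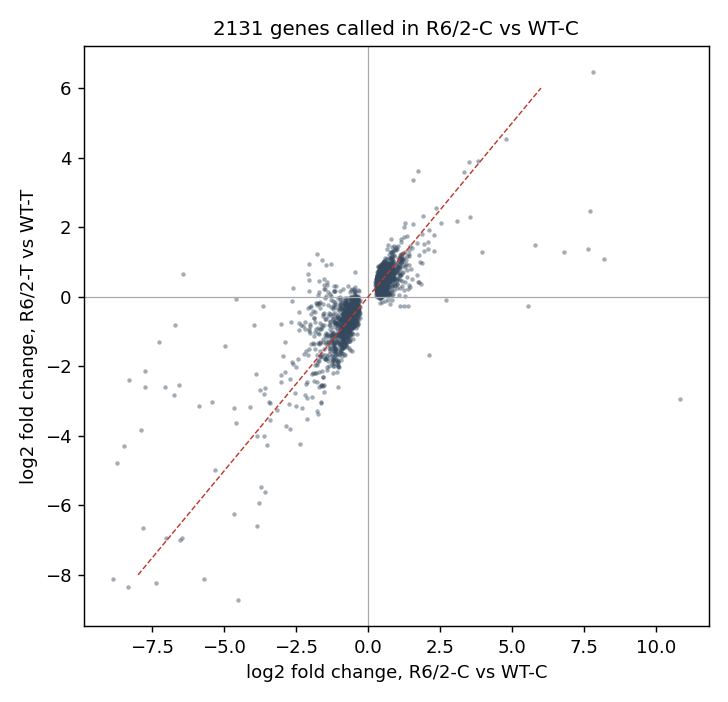
Log2 change of R6/2-C against WT-C (horizontal) and of R6/2-T against WT-T (vertical) for the 2131 genes called in the former, with the line of equal change dashed. Most points lie in the quadrants of equal sign.

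The interaction asked whether lowering TRAX acted differently in the 2 genotypes. Phf3 was the only gene called by edgeR, with a log2 change of 1.72 in R6/2 and −0.06 in WT (difference 1.79, SE 0.19, adjusted p = 0.0302). It was not called in recovered fragments (0.43, adjusted p = 0.263), after the GC and length correction (1.41, adjusted p = 0.0943), or without any 1 of WT-C 2, WT-C 3, R6/2-C 1, R6/2-C 3, WT-T 2, WT-T 3 or the R6/2-T libraries. In all 2751 genes had an unadjusted p under 0.05 and 153 were called by DESeq2 (105 higher), against 0 in recovered fragments, where 2735 had an unadjusted p under 0.05. Next by p came Pcdh20 (1.91, SE 0.24, adjusted p = 0.0723, and 0.06 in recovered fragments), the membrane skeleton gene Epb41 (1.15), Fkbp1a (−1.65) and Gm28941 (2.22), each of the latter with adjusted p = 0.204. The striatal genes had differences of −0.73 (SE 0.24, adjusted p = 0.354) for Ppp1r1b, −0.81 (SE 0.22, adjusted p = 0.353) for Adora2a, −0.56 (SE 0.21) for Drd2, −0.24 (SE 0.15) for Drd1, −0.40 (SE 0.20) for Tac1, −0.24 (SE 0.39) for Penk, 0.29 (SE 0.72) for Pde10a and 0.47 (SE 0.22) for Htt. Without R6/2-C 2 the count was 29, without WT-C 1 or WT-T 1 it was 3, and without R6/2-T 1 it was 2.

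With the preset correlation 15 of 30 lists were called for the interaction, 3 higher and 12 lower. None was with an estimated correlation (lowest adjusted p = 0.53). Interferon-stimulated genes differed by a median of −1.53 (camera adjusted p = 8.58e-11, adjusted p = 0.572 with an estimated correlation), with 6 of 25 at an unadjusted p under 0.05, and immediate-early genes by −0.70 (camera adjusted p = 1.16e-11, adjusted p = 0.53 with an estimated correlation), with 12 of 18. For these, edgeR called 0 over all genes, DESeq2 0 and 2, and 0 and 10 were lower when adjusted over the list alone. Small RNA genes, of which edgeR called 0 and DESeq2 1, differed by 0.28 (camera adjusted p = 0.000154, adjusted p = 0.572 with an estimated correlation), or 0.01 after the GC and length correction (camera adjusted p = 0.696), with 1 higher when adjusted over the list alone and 5 at an unadjusted p under 0.05.

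Across all genes tested, the shRNA changes of the genotypes correlated at r = 0.0484 and rho = 0.10, with no library shared and genes not being independent replicates. The r was −0.0485 without WT-C 3, 0.175 without WT-T 1 and 0.155 with at least 1 CPM in 3 libraries. The sign of the shRNA change was then counted in the 2131 genes that differed by genotype, to ask whether lowering TRAX moved them back. In R6/2, 964 (45.2%) had the sign opposite to the genotype difference, 1160 the same sign and 7 no direction. Counts simulated without shRNA effect or links between genes gave a mean of 67.3% opposite (64.2% to 68.9%, 20 draws), because R6/2-C is shared. For these genes the slope of shRNA change on genotype difference was −0.156, against a simulated mean of −0.127 (−0.145 to −0.104), which is more opposite. Over genes with a mean log2 CPM over 2 the covariance was 0.0284, against −0.0276, and r 0.192, against −0.252. Over all genes r was −0.136. Of the 2131 genes 1 was called in the opposite direction, Wnk1 (log2 −0.63 by genotype and 0.71 with the shRNA), and 2 in the same direction, Pdyn and Nptx2. For the 5304 genes called in R6/2-T against WT-T, where sharing acts the other way, 11.7% were opposite, against 36.5% in the simulation, with a slope of 0.549 against 0.0957 and, over genes with a mean log2 CPM over 2, a covariance of 0.156 against 0.0276. R6/2-C was also divided so that no library served both contrasts, which leaves 1 contrast a single R6/2-C library and spread from other groups. Of genes called by genotype 18.2% to 44.8% were opposite over the 6 ways, with slopes of 0.0376 to 0.158. Opposite were 34.1% without WT-C 1 and 64.9%, inside the simulated range, without R6/2-C 2.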

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

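The tests of explanations for the interferon, transcript length and Phf3 patterns were chosen after the result was seen, and the other splits of the libraries before it. The shRNA change differed between the genotypes by the interaction test for Phf3 (log2 1.79, SE 0.19, edgeR adjusted p = 0.0302). By camera at the preset correlation it differed for 15 gene lists. Among immune lists, the median difference was −1.53 for interferon-stimulated genes (camera adjusted p = 8.58e-11), −2.71 for lymphocyte and granulocyte markers (0.000166), −1.34 for antigen presentation genes (0.00726) and −0.57 for reactive glia and complement genes (0.00582). It was −0.72 for microglia markers (0.00768) and −0.76 for disease-associated microglia genes (0.00161). Among neuronal lists it was −0.16 for medium spiny neuron genes (0.0189), −0.70 for immediate-early genes (1.16e-11) and 0.16 for glutamate and postsynaptic genes (0.00726). It was 0.23 for double-strand break repair genes (0.00477), −0.31 for p53 targets (0.0194) and 0.28 for small RNA genes (0.000154). It was −0.24 for nuclear oxidative phosphorylation genes (4.95e-05), −0.40 for ribosomal protein genes (8.58e-11) and −0.42 for replication-dependent histone genes (0.00477). With an estimated correlation none of the 15 was called, with adjusted p from 0.53 to 0.595.

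In these 15 lists edgeR called 0 members over all genes and DESeq2 called 4, namely 2 immediate-early genes, 1 repair gene and 1 small RNA gene. Adjusted over the list alone, 10 immediate-early, 2 repair, 1 small RNA and 1 lymphocyte gene were called. Without any 1 of the 12 libraries 6 of the 15 lists were called, the interferon, immediate-early, repair, small RNA, oxidative phosphorylation and ribosomal lists. Without WT-T 1 the camera adjusted p was 0.2 for the microglia, lymphocyte, reactive glia and disease-associated microglia lists, 0.45 for antigen presentation and 0.718 for glutamate genes. It was 0.477 for medium spiny neuron genes without WT-T 3, and 0.125 for p53 targets without R6/2-C 3 and for histones without R6/2-C 1. Medians without 1 library went from −0.93 to 0.02 for reactive glia and 0.00 to 0.28 for glutamate genes, which leaves no settled direction, and from −3.20 to −1.15 for lymphocyte, −1.73 to −0.48 for antigen presentation, −1.12 to −0.30 for disease-associated microglia, −0.95 to −0.40 for microglia, −0.26 to −0.03 for medium spiny neuron, −0.70 to −0.14 for histone, −0.53 to −0.17 for ribosomal, −0.34 to −0.12 for oxidative phosphorylation and 0.18 to 0.39 for small RNA genes. After the GC and length correction the medians were 0.02 for glutamate, 0.07 for repair, 0.01 for small RNA, −0.03 for oxidative phosphorylation and −0.13 for histone genes, none of them called (camera adjusted p = 0.819, 0.522, 0.696, 0.531 and 0.112), and −0.15 for ribosomal genes. In recovered fragments the histone median was −0.15 (camera adjusted p = 0.306). Of 100 splits drawn from the 200 of the libraries within each genotype, 1 swapped the real labels of a single genotype and so measured the mean shRNA change, and it was left out after its value was seen. Of the other 99, the real one included, 16 called at least 15 lists, the highest other split 17, and 49 called at least 1 gene, the highest other split 5. Chance is not excluded for either count.

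Interferon-stimulated genes were lower in R6/2-T than in R6/2-C in all 25 cases, with a median of −1.71 (camera adjusted p = 4.88e-16, adjusted p = 0.47 with an estimated correlation). A bias with GC content and length as the whole cause is argued against by a median of −1.60 after that correction. Centred on group means, the interferon level went with the lymphocyte level over the 12 libraries (Pearson r = 0.857, exact permutation p = 0.000772, adjusted p = 0.0112 over 29 relations, and r = 0.814 without the 2 farthest libraries; Spearman rho = 0.86, exact p = 0.00231, adjusted p = 0.0313). It also rose with the reactive glia, disease-associated microglia, antigen presentation and microglia levels (r from 0.827 to 0.933) and fell as the interneuron level rose (r = −0.767, adjusted p = 0.0186). This is consistent with immune activity or immune cells differing between libraries of one group, with Cd74, abundant in antigen-presenting cells, from 181 to 1480 CPM inside WT-T and no sorting of cells named in the labels. An effect of TRAX shRNA in R6/2 striatum cannot be told apart from it, because the two-sided exact permutation p of the interferon level was 0.2, and 3 libraries against 3 cannot go below 0.1.

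Longer transcripts were higher in R6/2-T than in R6/2-C, with a Spearman rho of 0.555 between change and length across 13210 genes, which are not independent replicates. The length trend of libraries ranged by 0.535 inside R6/2-C, 0.962 of the shift of 0.556 to the R6/2-T mean. This rests on R6/2-C 2 (0.105, against −0.431 and −0.361). R6/2-T lay at 0.301 to 0.349, above all others (up to 0.119). RNA or library quality and an effect of TRAX shRNA in R6/2 striatum are not told apart. The two-sided exact permutation p of the trend was 0.1, the smallest for 3 against 3.

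Phf3 had 147 to 164 CPM in the R6/2-T libraries and 36.7 to 55.6 CPM in the other 9 in StringTie counts, and 22.5 to 24.3 against 7.62 to 11.5 in FPKM. In fragments recovered from the same libraries it had 164 to 185 against 110 to 152 CPM. The log2 change between R6/2-T and R6/2-C in fragments was 0.241 of that in StringTie counts, which suggests that the assignment of reads by the quantification tool accounts for part of it. An effect of TRAX shRNA in R6/2 striatum stays open, because the interaction was 0.43 in fragments with adjusted p = 0.263. The interaction call in StringTie counts was lost without R6/2-C 3 (adjusted p = 0.171) and without each of 8 other libraries, with adjusted p from 0.0509 to 0.134.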

How the results depend on the processing

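Which alternatives were chosen after seeing the data is given with the methods. No named gene that was called in either fit changed sign. Most called genes were higher for R6/2-C against WT-C (1142 and 989 lower), but lower in 10 of 22 other fits. For R6/2-T against R6/2-C (12 and 4) this turned in 7 of 22 and was even in 5. It turned in 1 of 22 for WT-T against WT-C, 4 of 22 for R6/2-T against WT-T and 2 of 27 for the interaction. Tsnax was called in every fit, with log2 changes without 1 library of −2.14 to −2.01 in R6/2 and −2.37 to −2.24 in WT. For R6/2-C against WT-C (2131 called genes) the count was 3437 by DESeq2, 3263 in fragments and 454 with only the 2 groups, where fewer libraries estimate the spread. For R6/2-T against R6/2-C (16) it was 1664 by DESeq2, 149 with at least 1 CPM in 3 libraries, where fewer genes are tested, and 7 with only the 2 groups, of which 4 were among the 16. It was 52 and 50 by limma on log2 of FPKM plus 1 and plus 0.1, 185 with an FPKM filter, 507 in fragments, 4 with 2 surrogate variables and 102 with counts divided by 4. For WT-T against WT-C (1) it was 101 by DESeq2, 2 with no filter, 3 with at least 1 CPM, 3 and 4 by limma on FPKM plus 1 and plus 0.1, 4 in fragments, 10 after the GC and length correction, 7 and 13 with 1 and 2 surrogate variables, and 3 with counts divided by 4. For R6/2-T against WT-T (5304) it was 3125 with 1 surrogate variable. For the interaction (1) it was 153 by DESeq2, 2 with no filter, 0 in fragments, 0 after the GC and length correction, and 6 and 2 with 1 and 2 surrogate variables. Lists called with an estimated correlation numbered 1 (R6/2-C against WT-C, of 16), 0 (R6/2-T against R6/2-C, of 18), 0 (WT-T against WT-C, of 7), 1 (R6/2-T against WT-T, of 20) and 0 (interaction, of 15), and by fry 9, 2, 0, 19 and 0. The correlation of shRNA changes (0.0484) was 0.155 with at least 1 CPM and 0.182 over genes with a mean log2 CPM over 2. The percent of genotype genes with the opposite sign (45.2) was 35.8 at adjusted p under 0.01 and 11.7 for genes called in R6/2-T against WT-T. With R6/2-C 1, R6/2-C 2 or R6/2-C 3 alone in the shRNA contrast and the others in the genotype contrast it was 36.4, 33.5 and 38.2, and the other way round 44.8, 18.2 and 34.6. In the authors' table, 4 genes were called, 137 had an adjusted p under 0.1 and 497 an unadjusted p under 0.05, as looser thresholds give more. Except where a construction is named, the cause was not tested.

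Leaving out 1 library, which leaves 2 in its group with the spread pooled, gave 803 to 2256 genes for R6/2-C against WT-C. For R6/2-T against R6/2-C it was 2 to 1197 (without R6/2-C 2) and for WT-T against WT-C 1 to 11 (without WT-T 1). For R6/2-T against WT-T it was 2760 to 4812 and for the interaction 0 to 29 (without R6/2-C 2). The lists called ranged from 12 to 17, 13 to 18, 5 to 11, 20 to 22 and 12 to 17 in the order above. The correlation ranged from −0.0485 (without WT-C 3) to 0.175, changing sign also without WT-T 3 (−0.0212), the percent opposite from 34.1 (without WT-C 1) to 64.9 (without R6/2-C 2), and the overlap with the authors' table from 1 to 180 (without R6/2-C 2). Of 3560 fits of named genes, 1672 under other settings and 1371 without 1 library stayed on the same side of the threshold, 160 and 323 lost a call, and 24 and 10 gained one. Of those that stayed, 42 differed in sign. A term for sex was not fitted, because all libraries carried the male pattern.

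With the replicate number as a replicate block, 1199, 4 and 0 genes were called for R6/2-C against WT-C, R6/2-T against R6/2-C and the interaction. Libraries sharing a number correlated in their deviations from the group means at −0.253 to 0.203, with 3 of 18 pairs over 0.1. Of 12 libraries 3 were closest to their own number, so pairing was neither seen nor excluded. Depth limits genes near the floor. Simulated recovery of 1.5-fold changes between R6/2-T and R6/2-C was 25.4% in genes with a mean log2 CPM over 2. This limits what a missing call can say.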

Other observations

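Genes named in these paragraphs were chosen after their values were seen, while the test of the mean shRNA change and the other splits of the libraries were chosen before. In StringTie counts edgeR called Tm9sf4, Tusc3 and Slc5a6 for the mean shRNA change of WT and R6/2, but in neither alone. Tm9sf4 (log2 −0.44, SE 0.05) and Tusc3 (log2 −0.59, SE 0.07) fell (both adjusted p = 0.0117). Slc5a6, a vitamin transporter, rose (log2 0.68, SE 0.08, adjusted p = 0.0165).

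The test of the mean of the 2 shRNA changes called 51 genes. A call does not show a shared change, since 1 genotype can carry the mean, as for Phf3. Both genotypes received the same hairpin, so effects of lowering TRAX and of the hairpin on other transcripts are not separated by the design.

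With 10 splits of 6 libraries, a share cannot be under 0.05. The other splits keep part of a group difference, so they do not measure chance. R6/2-C against WT-C called 2131 genes against 1 in the highest other split, and 16 lists against 21, matched by 1 and 3 of 10. R6/2-T against R6/2-C called 16 genes against 2 and 18 lists against 13, each matched by 1 of the 10, the real split itself. WT-T against WT-C called 1 gene against 15 and 7 lists against 20, matched by 5 and 9 of the 10. What gave the split with 15 genes was not tested. R6/2-T against WT-T called 5304 genes against 2 and 20 lists against 20, matched by 1 and 2 of the 10. The correlation of the shRNA changes was 0.0484 against −0.288 in the most extreme other split, and 60 of 99 splits gave an absolute value as large, so chance is not excluded.

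Ttr, a marker of choroid plexus that dissection can carry along, differed between libraries of one group, with 1540 CPM in R6/2-C 2 against 97 and 131 in R6/2-C 1 and R6/2-C 3, and 995 in WT-T 1 against 391 and 125 in WT-T 2 and WT-T 3. In R6/2-T it had 825, 969 and 1490 CPM, and in WT-C 293, 115 and 249.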
